A study of Mus musculus with 12 samples.

How the data were processed

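Gene expression was measured by stranded RNA-seq of polyadenylated RNA from mouse colonocytes, the epithelial cells that line the colon. Per the labels' protocols, RNA was taken with miRNeasy kits and libraries were made with the KAPA mRNA HyperPrep kit. The 12 libraries fall into 4 groups of 3: wild-type (WT) and knockout (KO) cells, each from untreated mice or from mice given dextran sodium sulfate (DSS), a polymer that injures the colon epithelium, at 3% for 3 days. The labels' treatment text names DSS for all 12 libraries while the treatment field reads none for 6 of them. The titles, the treatment field and the series' design text were followed. The labels do not say whether the libraries of a group came from separate mice, so p-values measure the spread between these libraries only.

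The authors deposited 2 tables, one for KO against WT in untreated mice and one for KO against WT under DSS. Per the submitters' processing notes, the reads were processed with TopHat2 2.1.1 and edgeR 3.30.3 on the builds GRCm38 and mm10. The read counter and the gene annotation are not given in the sources used here. Per the file headers, each table holds RPKM (reads scaled by gene length and library depth) for each library. The authors' log2 fold change and log2 mean abundance, their F score, their p-value and their false discovery rate stand beside the RPKM in the deposited tables, per the file headers. The deposited group columns headed RPKM hold CPM over a constant and were not used. Each table has 23794 gene lines. A spreadsheet turned 26 gene names into dates, and 4 lines whose date name occurs more than once were left out, leaving 23790 genes. No sample column was left unmapped.

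Within each gene the RPKM values of the libraries are whole multiples of the value of 1 read. Whole reads were recovered for 23790 genes (100%), with a tolerance of 0.02 reads. The recovered totals were 20606918 to 26839250 reads per untreated library and 12621697 to 16707030 per DSS library. The implied scaling factors of the authors ran from 0.972 to 1.03 in the untreated table and from 0.956 to 1.03 in the DSS table. No read fell on 5392 genes in the 12 libraries. At these depths 10846 to 11103 genes per library had an RPKM of 1 or more. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 22.9 to 86.5 and a Pearson r across genes of 0.989 to 0.997 on the log2 scale.

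The design, the gene lists, the rule for named genes and the other settings to be tried were fixed before the data were examined. The design assumed counts. Because the deposited unit is RPKM, its stated fallback was used: limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(RPKM + 1). Genes needed an RPKM of 1 or more in at least 3 of the compared libraries. Adjusted p-values are Benjamini-Hochberg values over the genes tested, and a gene was called at an adjusted p under 0.05. A fold change on the log2(RPKM + 1) scale understates the change of genes with low values. KO and WT were compared within each table, using the 6 libraries of that table. The interaction, whether the KO against WT difference itself differed between DSS and untreated mice, was fitted over the 12 libraries. Each difference in it is taken within a table, so a scaling factor of a table cancels up to the pseudocount. A KO against WT difference particular to the libraries of a single table does not cancel, so the interaction cannot tell DSS from batch. DSS was not tested against untreated mice, because the tables were normalised separately and their libraries carry different number series, so that batch and DSS cannot be told apart. Levels across tables are set side by side without a test.

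Of 42 fixed gene lists, 34 had at least 3 tested genes in each comparison. They were tested with limma's camera, which asks whether a list ranks apart from the other genes, 2-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison. The same test with an estimated correlation is given beside each call. The rule for named genes takes AA467197, Mir147 and Ndufa4 and, among called genes with a mean of 50 or more reads and no overlap between the groups, the 8 largest rises and the 8 largest falls. It adds up to 3 called members of each list and, where fewer than 5 genes were called, the 5 genes with the smallest p in each direction. Gene models, clone names and receptor segments were left out of the largest changes, and no overlap rule applied in the interaction. Other list members named as examples are among those with the smallest p in their list and were chosen after their values were seen. Some genes that the rule takes are not reported here. Mir147 and the genes of the mitochondrial genome were not analysed here. Positions come from GENCODE vM21 on GRCm38 and are 1-based.

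The fits were tested on simulated data with 50 genes changed at each of 4 fold sizes. At 2-fold, 94% of them were recovered in the untreated comparison (11056 genes), 76% in the DSS comparison (10987 genes) and 58% in the interaction (11282 genes). At 1.5-fold, 40%, 12% and 6% were recovered in those comparisons. Of all calls in them, 7.26%, 8.97% and 6.62% were false. A list raised on purpose was called in each simulated comparison and 0 other lists were. The simulated genes were drawn independently, whereas the estimated correlation within real lists reached 0.95 (MHC class II under DSS). The simulation therefore cannot show how often lists of correlated genes are called falsely.

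The other settings were other pseudocounts, filters and thresholds, a fit of all libraries, a replicate block and leaving out each library for the genes. Settings added after seeing the data were median-ratio scaling, limma voom on the recovered reads and a robust variance, which stood for other size factors, count tests and a robust fit on counts, the gene lists without each library, the trend with transcript length taken out of each library, and a Hox index of each library as a covariate. The index is the mean log2 level of Hox genes with paralog number 10 or more minus that of the others, with Hoxa13 and Hoxb8 left out. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the recovery of reads, permutation tests and plots.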

Results

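RNA-seq was used to ask how C15ORF48 and miR-147, which share one locus, control inflammation of the gut. Purified mouse colonocytes with the locus (WT) or without it (KO) were profiled from untreated and DSS-challenged mice, with 3 libraries in each of the 4 groups. The deposited RPKM values correspond to 20606918 to 26839250 reads per untreated library and 12621697 to 16707030 per DSS library.

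AA467197, the mouse gene of C15ORF48, was close to absent from every KO library. It held 6203, 6493 and 5851 reads in the WT untreated libraries and 89, 76 and 52 reads in the KO untreated libraries. Under DSS it held 4078, 4013 and 5304 reads in WT and 53, 75 and 90 reads in KO. The gene (ENSMUSG00000033213.16) lies on chromosome 2 from 122636986 to 122641191 on the plus strand. The miR-147 hairpin (Mir147, ENSMUSG00000076309.2) lies at 122640803 to 122640881, inside the 3′ UTR (122640767 to 122641191) in exon 5 of its transcript ENSMUST00000047498.14. Ndufa4, a subunit of cytochrome c oxidase, lies on chromosome 6 from 11900292 to 11907497 on the minus strand (ENSMUSG00000029632.7), and its 3′ UTR spans 11900292 to 11900537 in exon 4 of ENSMUST00000204978.2.

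**Figure D1:**
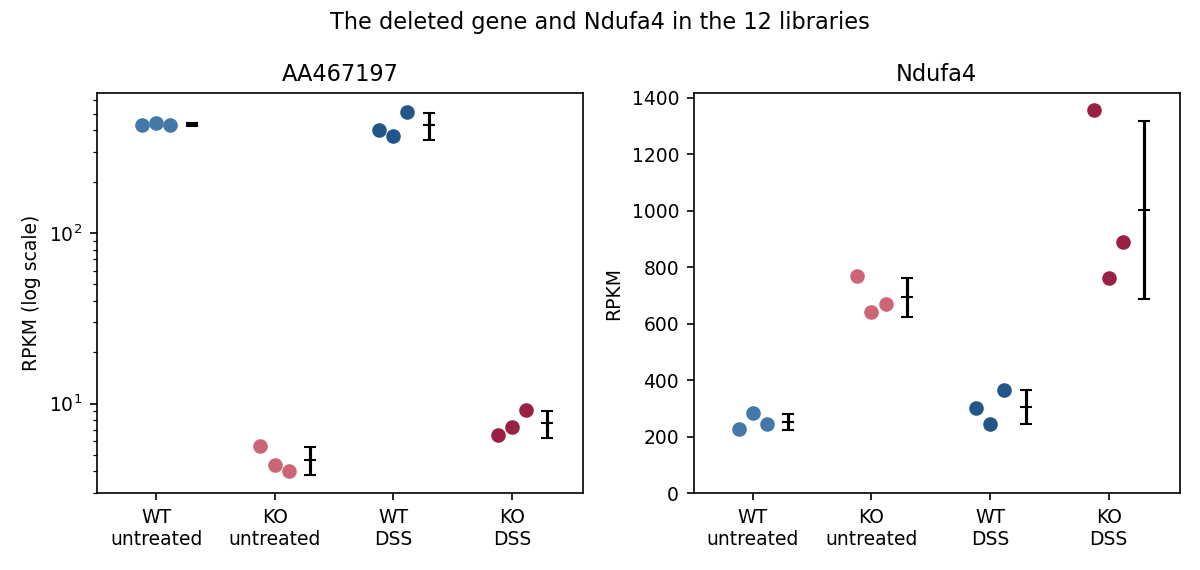
RPKM of AA467197 (left, log scale) and Ndufa4 (right, linear scale) in the 12 libraries, with the mean and SD of each group of 3 beside its points. For AA467197 the KO libraries sit between 4.03 and 9.19 and the WT libraries between 370.3 and 515, and for Ndufa4 each KO library lies above each WT library.

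**Figure D2:**
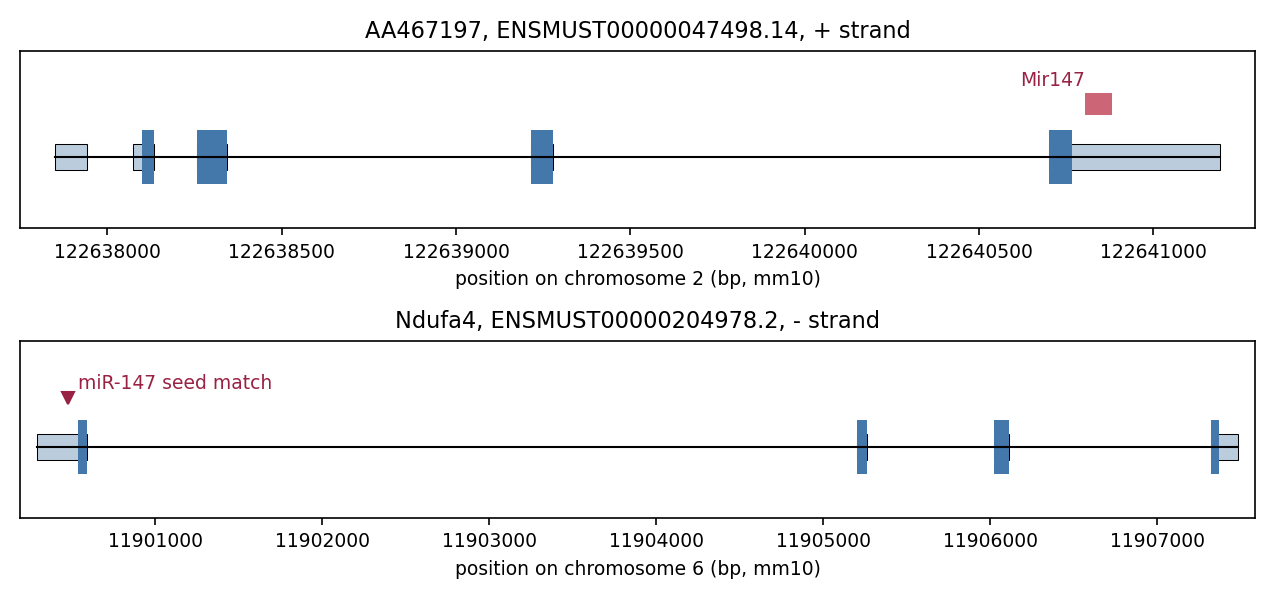
Transcripts of AA467197 and Ndufa4 on mm10, with coding exons as tall boxes, untranslated parts as low boxes and introns as lines; the horizontal axes give the position in bp. The miR-147 hairpin lies in the 3′ UTR of AA467197, and a 7-base match to the miR-147 seed lies at 11900476 to 11900482 in the 3′ UTR of Ndufa4.

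In colonocytes of untreated mice, loss of the locus changed 2 genes beyond the spread between libraries. AA467197 fell from 434 ± 7.11 to 4.68 ± 0.868 RPKM (SD, n = 3 per group), a log2 fold change of −6.27 (SE 0.11, limma adjusted p = 7.59e-08). Ndufa4 rose from 251 ± 28.1 to 693 ± 68.4 RPKM, a log2 fold change of 1.46 (SE 0.11, limma adjusted p = 0.00625), or 2.75-fold. As lists tested with a preset correlation, markers of small intestinal enterocytes and of deep crypt secretory cells were lower in KO, and interferon, MHC class II and glycolysis genes were higher. With an estimated correlation the adjusted p was 0.411 for small intestinal enterocytes and 0.868 for each of the others, and 0 of their members passed over all genes. The comparison asked what the locus does in the unchallenged colon.

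None of the other genes with the smallest p passed the test, each with an adjusted p of 0.459. Among them St8sia5, a sialyltransferase, had 1.39 ± 0.265 RPKM in WT and 5.12 ± 1.98 in KO (log2 fold change 1.31, SE 0.24). Banp (0.61), Cyp2d34 (0.59) and Gm9926 (0.44) also had positive log2 fold changes. Negative ones were seen for Zfp758 (−0.85), Gm7072 (−0.56), Mgat4c (−0.39) and Slc30a4 (−0.37), a zinc transporter gene that lies 40.0 kb from AA467197. Slc30a4 had 35.6 ± 1.02 RPKM in WT and 27.3 ± 0.667 in KO.

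Small intestinal enterocyte markers fell as a list in untreated KO, with 8 of 9 members below WT and a median log2 fold change of −0.47 (camera adjusted p = 2e-06). With an estimated correlation the adjusted p was 0.411. No member passed over all genes and 5 passed adjusted over the list alone, among them Fabp6, the ileal bile acid binding protein (23.8 ± 8.71 to 10.6 ± 1.06 RPKM), and Alpi, intestinal alkaline phosphatase (22.6 ± 6.25 to 13.8 ± 1.21). Deep crypt secretory cell markers were lower in 7 of 8 members, with a median of −0.85 (camera adjusted p = 0.00733, adjusted p = 0.868 with an estimated correlation). Reg4, the marker that names these cells, passed adjusted over the list alone (864 ± 189 to 452 ± 88.6 RPKM). Retnlb had 791 ± 717 and 126 ± 75.9 RPKM and Ang4 1519 ± 1547 and 237 ± 256 in WT and KO, and neither passed. Tuft cell markers had 1 of 13 members above 0 and a median of −0.17 (camera adjusted p = 0.03, adjusted p = 0.868 with an estimated correlation), with Rgs13 lower adjusted over the list alone (7.52 ± 0.626 to 4.94 ± 0.458 RPKM). Cholesterol synthesis had 2 of 22 members above 0 and a median of −0.07 (camera adjusted p = 0.0221, adjusted p = 0.868 with an estimated correlation), with 0 members called adjusted over the list alone. The small intestinal list kept its call without each library in turn. The deep crypt list was not called without WT untreated replicate 2 (−0.60) or 3 (−0.89), nor the tuft list without WT untreated replicate 2 (−0.07) or 3 (−0.02) or KO untreated replicate 2 (−0.05), and the tuft median was −0.30 without WT untreated replicate 1 and −0.26 without KO untreated replicate 5. The cholesterol list was not called without WT untreated replicate 2 (0.03) or KO untreated replicate 4 (−0.08) or 5 (−0.10), and its median was −0.17 without WT untreated replicate 1 and −0.13 without KO untreated replicate 2.

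The interferon response list had 26 of 27 members above 0 and a median of 0.18 (camera adjusted p = 0.00335, adjusted p = 0.868 with an estimated correlation). Its immunoproteasome gene Psmb9 had 20.1 ± 1.75 RPKM in WT and 25 ± 1.46 in KO. All 6 MHC class II genes tested were above 0, with a median of 0.43 (camera adjusted p = 0.0221, adjusted p = 0.868 with an estimated correlation). Cd74, the invariant chain, had 5.69 ± 1.86 and 15.5 ± 13.8 RPKM. In neither list was a member called adjusted over the list alone. Glycolysis had 12 of 14 members above 0 and a median of 0.12 (camera adjusted p = 0.00733, adjusted p = 0.868 with an estimated correlation). Pyruvate kinase Pkm passed adjusted over the list alone (208 ± 1.68 to 258 ± 10.8 RPKM). Without WT untreated replicate 2 the interferon (0.08), MHC class II (0.34) and glycolysis (0.12) lists were not called, nor was the interferon list without KO untreated replicate 5 (0.01) or MHC class II without KO untreated replicate 4 (0.09). The interferon median was 0.32 without KO untreated replicate 2.

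Respiratory complex I had 32 of 35 subunit genes above 0 at a median of 0.07 (camera adjusted p = 0.0212, adjusted p = 0.868 with an estimated correlation), and 0 were called adjusted over the list alone. Complex IV had 12 of 13 above 0 at a median of 0.06 and a mean of 0.19 (camera adjusted p = 0.0273, adjusted p = 0.868 with an estimated correlation). Its called member was Ndufa4 on both counts, and the list was not tested without Ndufa4 here or under DSS. The tricarboxylic acid cycle list had 11 of 14 above 0 at a median of 0.10 (camera adjusted p = 0.0425, adjusted p = 0.868 with an estimated correlation), and 0 were called adjusted over the list alone. Shorter transcripts sat slightly higher in KO throughout, with a median log2 fold change of 0.05 in the tenth of genes with the shortest transcripts and −0.10 in the tenth with the longest. With that trend taken out, the medians of complex I, complex IV and the tricarboxylic acid cycle were 0.01, 0.00 and 0.07 and none of them was called. Complex I was not called without WT untreated replicate 3 (0.04) or KO untreated replicate 2 (0.02). Complex IV was not called without WT untreated replicate 2 (0.06) or 3 (0.02) or KO untreated replicate 2 (0.05) or 5 (0.09), and its median was 0.09 without WT untreated replicate 1 or KO untreated replicate 4. The tricarboxylic acid cycle was not called without WT untreated replicate 1 (0.09) or 2 (0.08) or KO untreated replicate 4 (0.08) or 5 (0.10).

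Of 11072 genes tested, 1006 had an unadjusted p under 0.05 (431 higher, 575 lower) where 553.6 would by chance, and in 16.0% the groups did not overlap where 10% would by chance. The authors' deposited table has 2 genes at a false discovery rate under 0.05, which are the same genes, and it marks 43 genes as up and 73 as down at an unadjusted p under 0.05 and a fold of 1.5 or more. Without WT untreated replicate 1 the count of called genes was 6 in place of 2.

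Under DSS, KO colonocytes differed from WT in 84 genes, 49 higher and 35 lower. Saa3, a serum amyloid A gene of the acute phase response, rose from 4.94 ± 0.588 to 28.1 ± 10.8 RPKM (log2 fold change 2.22, SE 0.26, limma adjusted p = 0.0287). Slpi, a secreted inhibitor of leukocyte proteases, rose from 3.3 ± 1.92 to 15.4 ± 6.75 RPKM (1.94, SE 0.34, adjusted p = 0.0463). AA467197 fell from 429 ± 76.0 to 7.69 ± 1.36 RPKM (−5.63, SE 0.17, adjusted p = 7.89e-07), and Ndufa4 rose from 303 ± 60.2 to 1002 ± 315 RPKM (1.70, SE 0.25, adjusted p = 0.034). As lists tested with a preset correlation, respiratory chain, interferon, MHC class II, xenobiotic and cell cycle genes were higher in KO, and crypt stem cell markers were lower. With an estimated correlation the adjusted p was 0.59 for ATP synthase and 0.561 for each of the others, and over all genes 4 xenobiotic members, 1 of complex IV (Ndufa4) and 0 of the others passed.

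Mal, a protein of apical membrane sorting, rose from 14.3 ± 4.80 to 119.6 ± 87.3 RPKM (log2 fold change 2.79, SE 0.44, adjusted p = 0.034). St3gal5, the GM3 ganglioside synthase, rose from 0.347 ± 0.176 to 8.77 ± 6.72 RPKM (2.66, SE 0.38, adjusted p = 0.034). For Mal and St3gal5 the spread within KO DSS was large beside the mean, and the authors' deposited table gives them false discovery rates of 0.15 and 0.0507. In untreated mice, in a table that was normalised separately, St3gal5 had 11.3 ± 5.54 RPKM in WT and 8.83 ± 1.55 in KO, and Mal 61.2 ± 19.5 and 51.2 ± 14.1. The hormone gene Sct had 33.0 ± 9.60 and 31.1 ± 7.68 RPKM there and C1qa 3.87 ± 1.77 and 3.07 ± 0.669, and for each of these 4 genes WT DSS had the lowest of the 4 group means.

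The largest falls other than AA467197 were in Wdfy1, an endosomal FYVE-domain protein (21.3 ± 4.86 to 4.28 ± 1.29 RPKM; log2 fold change −2.08, SE 0.21, adjusted p = 0.0221), and Itih2, an inter-alpha-trypsin inhibitor heavy chain (−1.50). B4galnt3, a glycosyltransferase (−1.37), Nxpe4 (−1.33) and Ano1, a calcium-activated chloride channel (52.2 ± 12.2 to 21 ± 4.38 RPKM; −1.27), also fell. Lrrc31 (−1.18), Npy1r, a neuropeptide Y receptor (−1.17), and Pla2g2a, a secreted antibacterial phospholipase (4.47 ± 1.16 to 1.52 ± 0.418 RPKM; −1.11), completed the named falls. From Itih2 on, the adjusted p-values of these falls were 0.0309 to 0.0478.

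**Figure D3:**
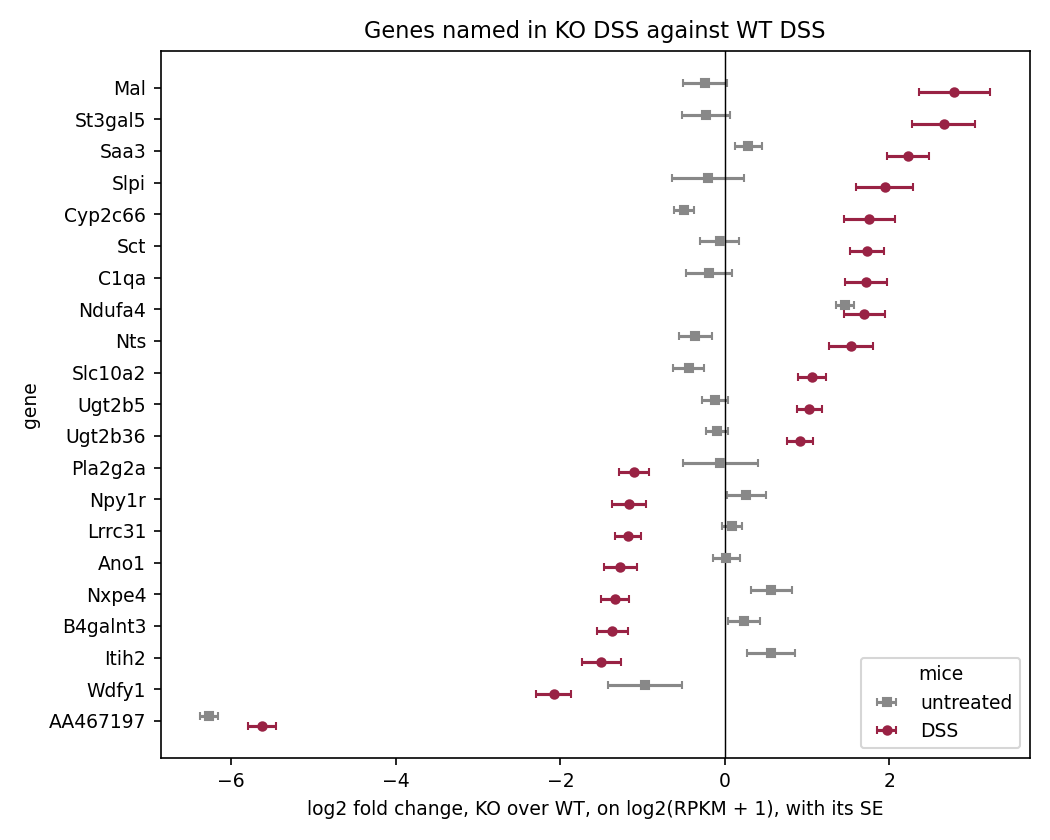
Log2 fold change of KO over WT on the log2(RPKM + 1) scale with its SE, for genes named under DSS, in untreated mice (grey squares) and under DSS (red circles), 3 libraries per group. AA467197 and Ndufa4 lie far from 0 in both, at −6.27 and 1.46 in untreated mice and −5.63 and 1.70 under DSS.

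Of the antimicrobial and acute phase list 15 of 21 members were above 0 at a median of 0.56 (camera adjusted p = 0.0247, adjusted p = 0.561 with an estimated correlation). Saa3 and Slpi rose and Pla2g2a fell over all genes, and the same counts of 2 up and 1 down held adjusted over the list alone. Reg3b, a bactericidal lectin, had 1853 ± 2069 RPKM in WT and 5391 ± 776 in KO and did not pass. Interferon response genes had 31 of 32 members above 0 at a median of 0.57 (camera adjusted p = 3.02e-08, adjusted p = 0.561 with an estimated correlation). Psmb9 (24.0 ± 3.86 to 45.8 ± 14.7 RPKM) and Psmb8 (34.4 ± 3.20 to 62.3 ± 19.3) were the 2 members called adjusted over the list alone, and 0 were called over all genes. All 6 MHC class II genes were above 0 at a median of 1.13 (camera adjusted p = 0.00127, adjusted p = 0.561 with an estimated correlation), with 3 called adjusted over the list alone. Among these H2-Ab1 had 5.08 ± 0.919 and 20.4 ± 14.8 RPKM. Without KO DSS replicate 3 the medians of these lists were 0.31, 0.36 and 0.52, and the antimicrobial list was not called without it, without KO DSS replicate 2 (0.51) or without WT DSS replicate 2 (0.30). The MHC class II median was 1.87 without KO DSS replicate 1. With the trend with transcript length taken out, the antimicrobial list (0.41, adjusted p = 0.201) was not called.

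Markers of immune cells moved beside these groups. The macrophage and dendritic cell list had 7 of 8 tested members above 0 at a median of 0.57 (camera adjusted p = 0.000721, adjusted p = 0.561 with an estimated correlation). C1qa, a complement component made by macrophages, rose from 0.167 ± 0.142 to 3.01 ± 1.67 RPKM (log2 fold change 1.71, SE 0.26, adjusted p = 0.034), and 5 members were called adjusted over the list alone, among them Lyz2 (1.68 ± 0.581 to 4.95 ± 2.41 RPKM). T and intraepithelial lymphocyte markers had 12 of 14 members above 0 at a median of 0.39 (camera adjusted p = 0.00127, adjusted p = 0.561 with an estimated correlation). Of these 6 were called adjusted over the list alone, such as Cd3e (1.85 ± 0.438 to 3.35 ± 0.650 RPKM), and 0 over all genes. Without KO DSS replicate 3 the medians were 0.31 and 0.22, and with the length trend taken out the T cell list (0.30, adjusted p = 0.0967) was not called. The summed level of 17 pan-leukocyte genes was 130.0 ± 8.88 CPM in WT DSS and 165 ± 42.9 in KO DSS.

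The respiratory chain was higher in KO DSS as lists, with Ndufa4 as the only member called over all genes or adjusted over its list alone. Complex I had 34 of 35 genes above 0 at a median of 0.34 (camera adjusted p = 1.49e-06, adjusted p = 0.561 with an estimated correlation), and Ndufs4 had 82.3 ± 14.5 and 127 ± 33.6 RPKM. Complexes II and III had 13 of 14 above 0 at 0.36 (camera adjusted p = 0.00143, adjusted p = 0.561 with an estimated correlation), and complex IV 13 of 13 at 0.49 (camera adjusted p = 0.000115, adjusted p = 0.561 with an estimated correlation). Cox7b had 344 ± 60.4 and 555 ± 163 RPKM. ATP synthase had 13 of 14 above 0 at 0.37 (camera adjusted p = 0.00444, adjusted p = 0.59 with an estimated correlation). Without KO DSS replicate 1 these medians were 0.20, 0.22, 0.27 and 0.19, and ATP synthase was not called. Transcript length went with this shift: the median log2 fold change was 0.24 in the tenth of genes with the shortest transcripts (median length 1009 bases) and −0.24 in the tenth with the longest (8036 bases). With the length trend taken out, the medians of complex I, complexes II and III, complex IV and ATP synthase were 0.15, 0.19, 0.25 and 0.13, with adjusted p-values of 0.00777, 0.0182, 0.00777 and 0.0645.

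Fatty acid oxidation and ketogenesis genes had 22 of 25 members above 0 at a median of 0.14 (camera adjusted p = 0.00169, adjusted p = 0.561 with an estimated correlation). Oxidative stress genes had 17 of 18 above 0 at 0.25 (camera adjusted p = 0.0224, adjusted p = 0.561 with an estimated correlation). In both lists 0 members were called adjusted over the list alone, and the oxidative stress list was not called without WT DSS replicate 2 (0.14) or KO DSS replicate 3 (0.15). Its median was 0.42 without WT DSS replicate 3 and 0.38 without KO DSS replicate 2, where that of fatty acid oxidation was 0.26 and 0.23, and with the length trend taken out the oxidative stress list (0.18, adjusted p = 0.119) was not called. Xenobiotic metabolism had 20 of 26 above 0 at 0.53 (camera adjusted p = 3.96e-06, adjusted p = 0.561 with an estimated correlation), with 4 members called over all genes and 12 adjusted over the list alone. Among these rises were Cyp2c66 (1.76), the glucuronosyltransferases Ugt2b5 (13 ± 1.99 to 27.5 ± 3.57 RPKM; 1.03) and Ugt2b36 (0.91), and Cyp2c65 (89.9 ± 20.8 to 217 ± 53.4 RPKM; 1.26).

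Absorptive colonocyte markers were above 0 in 16 of 16 members at a median of 0.34 (camera adjusted p = 0.00127, adjusted p = 0.561 with an estimated correlation). Fabp2, a fatty acid binding protein, was 1 of 2 called adjusted over the list alone (408 ± 116 to 837 ± 63.4 RPKM). Enteroendocrine markers had 15 of 17 above 0 at 0.24 (camera adjusted p = 0.000754, adjusted p = 0.561 with an estimated correlation), with 2 called over all genes and 5 adjusted over the list alone. The hormone genes Sct (secretin, 9.80 ± 0.933 to 35.7 ± 10.3 RPKM; 1.73) and Nts (neurotensin, 10.6 ± 3.65 to 32.7 ± 10.2; 1.53) rose. Small intestinal enterocyte markers had 6 of 9 above 0 at 0.52 (camera adjusted p = 0.0247, adjusted p = 0.561 with an estimated correlation), with 1 called over all genes and 3 adjusted over the list alone. Slc10a2, the ileal bile acid transporter, rose from 23.9 ± 3.73 to 51.1 ± 10.4 RPKM (1.06, SE 0.17, adjusted p = 0.037). Crypt stem cell markers had 3 of 12 above 0 at −0.37 (camera adjusted p = 0.00747, adjusted p = 0.561 with an estimated correlation) and 0 called adjusted over the list alone; Axin2, a Wnt target, had 5.76 ± 0.735 and 3.79 ± 0.740 RPKM. Without WT DSS replicate 1 the small intestinal list had a median of 0.31 and was not called, its median was 0.80 without WT DSS replicate 3 and 0.32 without KO DSS replicate 1, and without WT DSS replicate 2 the crypt stem list (−0.19) was not called and the absorptive median was 0.15. Without KO DSS replicate 1 the crypt stem list (−0.29) was not called either and the enteroendocrine median was 0.10. With the length trend taken out, the small intestinal (0.65), enteroendocrine (0.15) and crypt stem (−0.16) lists were not called, with adjusted p-values of 0.131, 0.0517 and 0.0536.

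Cell cycle genes had 27 of 30 members above 0 at a median of 0.30 (camera adjusted p = 6.22e-06, adjusted p = 0.561 with an estimated correlation), and Cdk1 (4.90 ± 0.908 to 8.54 ± 0.747 RPKM) was 1 of 3 called adjusted over the list alone. Cell death genes had 17 of 23 above 0 at 0.25 (camera adjusted p = 0.00127, adjusted p = 0.561 with an estimated correlation). In this list 0 members were called adjusted over the list alone. Wound repair genes had 14 of 17 above 0 at 0.27 (camera adjusted p = 0.00406, adjusted p = 0.561 with an estimated correlation), with Emp1 and Sprr1a called adjusted over the list alone. With the length trend taken out, the wound repair median was 0.13 and the list was not called (adjusted p = 0.0907). The wound repair median was 0.16, 0.42 and 0.43 without WT DSS replicate 2, WT DSS replicate 3 or KO DSS replicate 2, and that of the cell cycle list was 0.46 without KO DSS replicate 1. Cytokines and chemokines were not called (10 of 13 above 0, median 0.36, camera adjusted p = 0.0685), with 3 members up and 1 down adjusted over the list alone. Among these Cxcl10 had 1.42 ± 0.625 and 3.47 ± 1.34 RPKM and Ccl28 69.4 ± 5.38 and 47.6 ± 3.38. NF-kappaB feedback (−0.10), goblet cell (−0.05), tight junction (0.01), unfolded protein (0.05) and p53 target (0.12) lists were not called, with adjusted p-values of 0.317, 0.921, 0.711, 0.384 and 0.704. The mean of the goblet cell list had the other sign (0.01).

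**Figure D4:**
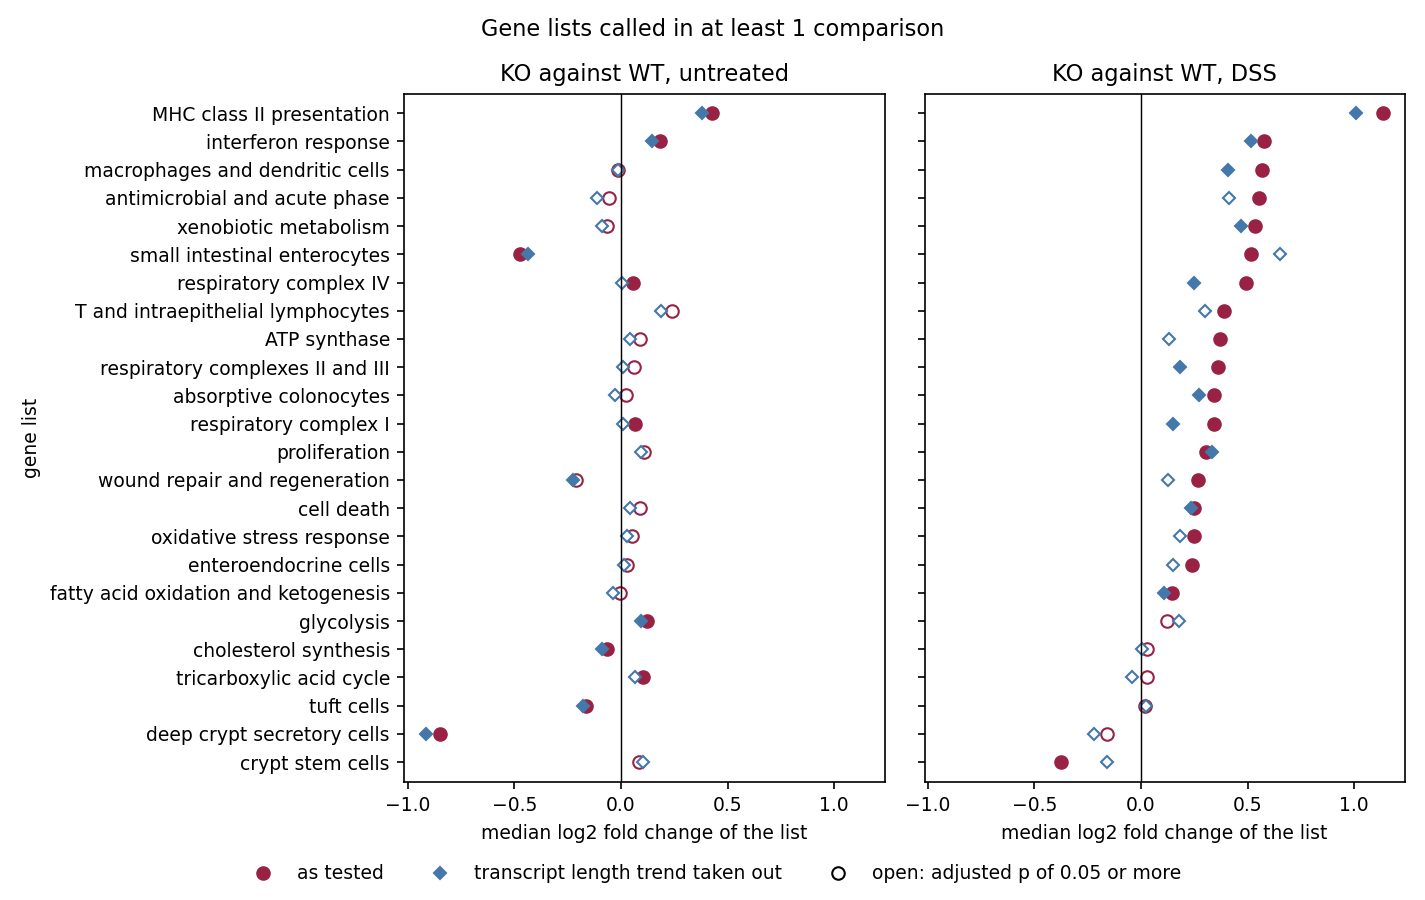
Median log2 fold change of KO over WT for the lists called in at least 1 of the untreated (left) and DSS (right) comparisons, as tested (circles) and with the transcript length trend taken out (diamonds); filled symbols have an adjusted p under 0.05. Under DSS the lists range from −0.37 for crypt stem cells to 1.13 for MHC class II presentation.

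Hox genes, whose paralog number follows position along the body axis, also separated the DSS groups. Hoxa13 (log2 fold change −0.86 on log2(RPKM + 0.1) under DSS) and Hoxb8 (1.01) were left out because their calls had been seen. Of the other Hox genes with a mean of 10 or more reads, all 7 with a paralog number of 10 or more were lower in KO DSS. Their median log2 fold change was −1.64, and the 17 others had a median of 0.28 with 11 above 0. Spearman's rho of paralog number and fold change, across 24 genes that are not independent replicates, was −0.67 (2-sided permutation p = 0.00066). In untreated mice it was 0.07 (permutation p = 0.743). The order was not seen within the Hoxa cluster, where 6 of 7 genes with lower numbers were also below 0, whereas 7 of 7 such Hoxb genes and 3 of 3 such Hoxd genes were above 0. Each KO DSS library had a lower Hox index (0.24, −0.47 and −0.43) than each WT DSS library (0.98, 1.76 and 1.17). Because the index separates the DSS groups, a fit with it as a covariate cannot tell region from genotype. In that fit the median SE of the genes called before rose from 0.16 to 0.39. The proliferation and absorptive lists turned to −0.49 and −0.52, and the interferon, MHC class II and antimicrobial lists to −0.26, −0.57 and −0.56 without a call. Glycolysis (−0.36), cholesterol (−0.39), NF-kappaB feedback (−0.40) and water and ion transport (−0.61), not called before, were called below 0. Of the 19 lists 8 kept their call and direction, among them the respiratory lists at the preset correlation. The fatty acid oxidation (0.09), macrophage (0.09), oxidative stress (−0.06), cell death (−0.21), wound repair (−0.01) and crypt stem (0.08) lists were not called with the index as a covariate. In untreated mice the complex IV, tricarboxylic acid cycle, cholesterol and MHC class II lists were not called with it either, each with an adjusted p of 0.0503.

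**Figure D5:**
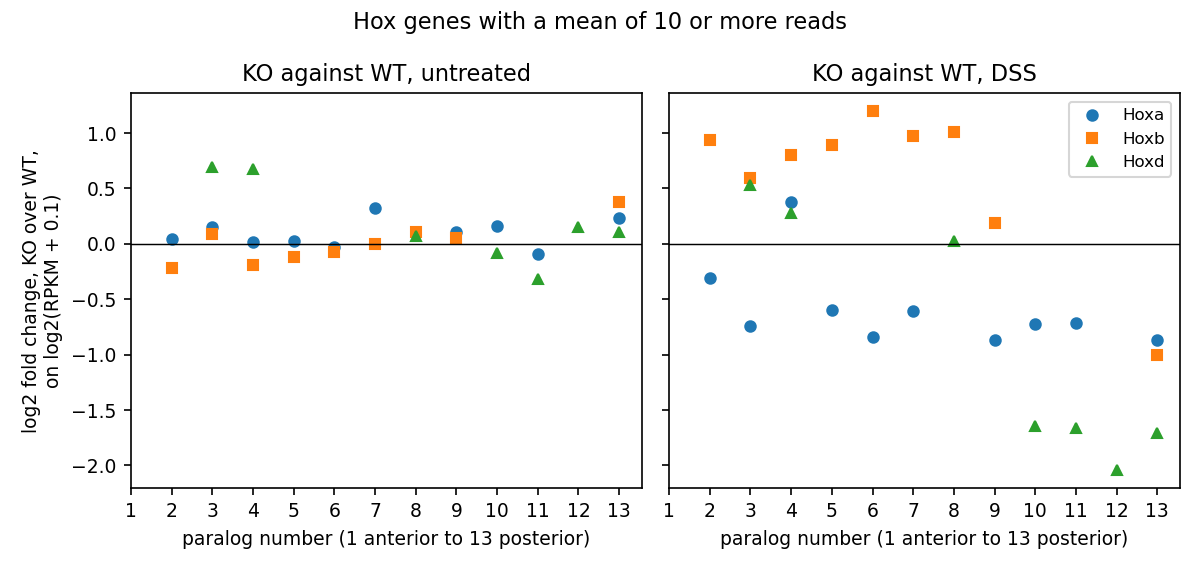
Log2 fold change of KO over WT on log2(RPKM + 0.1) against the paralog number of each Hox gene with a mean of 10 or more reads, in untreated mice (left) and under DSS (right); Hoxa13 and Hoxb8 are drawn here but were left out of the rank test because their calls had been seen. Under DSS the genes numbered 10 or more lie below 0, Hoxb genes 2 to 9 above 0 and most Hoxa genes below 0 whatever their number.

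Of 10990 genes tested under DSS, 2053 had an unadjusted p under 0.05 (1083 higher, 970 lower) where 549.5 would by chance, and in 23.0% the groups did not overlap where 10% would by chance. The authors' deposited table has 206 genes at a false discovery rate under 0.05 (101 higher, 105 lower), which include 79 of the 84, and marks 198 up and 117 down at an unadjusted p under 0.05 and a fold of 2 or more. The count of 84 was 2, 1 and 37 without WT DSS replicate 1, 2 or 3, and 364, 47 and 5 without KO DSS replicate 1, 2 or 3. It was 1 with the Hox index as a covariate and 250 with the length trend taken out.

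Whether the KO effect itself differed between the DSS and the untreated libraries was tested as an interaction. In it 158 of 11306 genes passed, 84 with a higher and 74 with a lower KO effect in the DSS libraries. Batch goes with DSS here, so the interaction cannot tell an influence of DSS from that of batch. Scnn1a, a subunit of the epithelial sodium channel, had 50.2 ± 0.791 and 58.7 ± 4.07 RPKM in untreated WT and KO and 50.5 ± 1.81 and 32.5 ± 2.85 under DSS (interaction log2 −0.85, SE 0.13, limma adjusted p = 0.0331). Adh1, an alcohol dehydrogenase, had 498 ± 129 and 696 ± 109 RPKM in untreated WT and KO and 995 ± 109 and 477 ± 159 under DSS (−1.61, SE 0.34, adjusted p = 0.041). Fabp2 had 784 ± 93.1 and 646 ± 58.1 RPKM in untreated WT and KO and 408 ± 116 and 837 ± 63.4 under DSS (1.35, SE 0.26, adjusted p = 0.0356). The KO effect did not differ detectably for AA467197 (0.64, SE 0.21, adjusted p = 0.129) or Ndufa4 (0.23, SE 0.29, adjusted p = 0.688).

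Large positive interactions were found for Mal (3.03), St3gal5 (2.89), Enpep, an aminopeptidase (2.32), Cyp2c66 (2.25), Ncoa7 (2.0), Saa3 (1.94) and C1qa (1.91). The largest negative ones were in Itih2 (−2.06), Nxpe4 (−1.90), AI854703 (−1.81), St6galnac4 (−1.72), Adh1, Cyp2d12 (−1.61), B4galnt3 (−1.60) and Hid1 (−1.53). Ncoa7 had 18.0 ± 5.72 and 10.9 ± 2.27 RPKM in untreated WT and KO and 8.58 ± 2.62 and 22.9 ± 3.47 under DSS. Hid1 had 37.5 ± 2.31 and 47.6 ± 3.47 RPKM in untreated WT and KO and 51.6 ± 10.4 and 23.2 ± 10.9 under DSS.

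Small intestinal enterocyte markers had 9 of 10 interactions above 0 at a median of 0.93 (camera adjusted p = 0.000202, adjusted p = 0.218 with an estimated correlation), with Slc10a2 called over all genes and 6 members adjusted over the list alone. Xenobiotic genes had 19 of 27 above 0 at 0.52 (camera adjusted p = 0.000202, adjusted p = 0.667 with an estimated correlation), with 7 called over all genes and 11 up and 1 down adjusted over the list alone. Wound repair genes had 13 of 17 above 0 at 0.37 (camera adjusted p = 0.00316, adjusted p = 0.667 with an estimated correlation). Sprr1a, a cornified envelope protein, was called (21.3 ± 6.36 and 12.4 ± 1.48 RPKM in untreated WT and KO, 8.16 ± 1.88 and 13.6 ± 2.16 under DSS), and 4 members were called adjusted over the list alone. Macrophage markers had 7 of 8 above 0 at 0.75 (camera adjusted p = 0.009, adjusted p = 0.667 with an estimated correlation), with C1qa called over all genes and 2 members adjusted over the list alone. Cell death genes had 20 of 23 above 0 at 0.17 (camera adjusted p = 0.009, adjusted p = 0.667 with an estimated correlation), with 1 member called over all genes and 1 adjusted over the list alone. These 5 lists kept their calls without each library in turn, with a xenobiotic median of 0.34 without KO DSS replicate 1 and cell death medians of 0.31 and 0.33 without KO DSS replicate 2 or 3. The macrophage list was not called with the length trend taken out (0.58, adjusted p = 0.0868) or with the Hox index as a covariate (0.24), nor the cell death list with the index (0.28).

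Interaction medians were also above 0 and called for complex I (0.29), complexes II and III (0.37), complex IV (0.32) and fatty acid oxidation (0.21), with camera adjusted p-values of 0.000622, 0.011, 0.011 and 0.00914 and an adjusted p of 0.667 for each with an estimated correlation. The antimicrobial (0.65), interferon (0.39), proliferation (0.25), absorptive (0.46) and enteroendocrine (0.15) lists had camera adjusted p-values of 0.011, 0.00428, 0.009, 0.0137 and 0.049, and an adjusted p of 0.667 for each with an estimated correlation. Water and ion transport had 4 of 20 members above 0 at −0.32 (camera adjusted p = 0.016, adjusted p = 0.667 with an estimated correlation), with Scnn1a called over all genes and 1 up and 5 down adjusted over the list alone. Crypt stem cell markers had 0 of 12 above 0 at −0.30 (camera adjusted p = 0.00914, adjusted p = 0.667 with an estimated correlation). Adjusted over the list alone, 3 antimicrobial, 3 absorptive, 3 enteroendocrine and 2 proliferation members were called, 1 each of complexes II and III and of fatty acid oxidation, and 0 of complex I, complex IV, interferon and crypt stem genes. With the length trend taken out the medians of complex I and complexes II and III were 0.14 and 0.18, and complex IV (0.19), antimicrobial (0.43) and enteroendocrine (0.12) lists were not called, with adjusted p-values of 0.0968, 0.0968 and 0.278. With the Hox index as a covariate fatty acid oxidation (0.25), antimicrobial (0.29), interferon (−0.03), proliferation (0.12) and absorptive (0.15) lists were not called.

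Most of these calls rested on single libraries. Without KO DSS replicate 1 complex I (0.10), complexes II and III (0.15), complex IV (0.17), water and ion transport (−0.26), crypt stem (−0.28) and enteroendocrine (−0.02) lists were not called. Without WT DSS replicate 2 complexes II and III (0.25), complex IV (0.27), fatty acid oxidation (0.16), antimicrobial (0.31), absorptive (0.30) and crypt stem (−0.18) lists were not called, and the proliferation median was 0.14. Interferon genes were not called without KO untreated replicate 2 (0.26), where KO DSS replicate 3 left out gave 0.26 with a call. Proliferation was not called without WT untreated replicate 2 (0.09) or KO DSS replicate 2 (0.20), and had 0.13 without KO untreated replicate 4. Absorptive markers were not called without WT untreated replicate 1 (0.42) or KO DSS replicate 2 (0.39). The antimicrobial list was not called without KO DSS replicate 3 (0.58), and had 1.06 and 0.41 without WT DSS replicate 3 or KO untreated replicate 4. Enteroendocrine markers were also not called without WT untreated replicate 1 (0.22) or 3 (0.02), WT DSS replicate 3 (0.12) or KO untreated replicate 2 (0.08) or 5 (0.12), and had 0.26, 0.23 and 0.28 without WT untreated replicate 2, KO untreated replicate 4 or KO DSS replicate 2.

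In the interaction 2152 genes had an unadjusted p under 0.05 where 565.3 would by chance, and the median interaction was 0.19 for the tenth of genes with the shortest transcripts and −0.14 for the tenth with the longest. The count of 158 was 43, 39 and 2 without WT untreated replicate 1, 2 or 3, and 1, 4 and 1 without KO untreated replicate 2, 4 or 5. Under DSS it was 1, 2 and 300 without WT DSS replicate 1, 2 or 3 and 433 and 2 without KO DSS replicate 1 or 3, and it was 0 with the Hox index as a covariate.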

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

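The tests with the transcript length trend taken out, with the Hox index as a covariate on the called genes and on the mean respiratory level, and of the gain of C1qb and C1qc beside that of C1qa were chosen only after the results they bear on were seen. The results below stand here because the KO effect under DSS differed from that in untreated mice in a test of the difference itself. That test cannot tell DSS from batch.

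The interaction called 158 genes and 16 gene lists. Positive interactions on the log2 scale were found for Mal (3.03), St3gal5 (2.89), Enpep (2.32), Cyp2c66 (2.25), Ncoa7 (2.0), Saa3 (1.94), C1qa (1.91), Nts (1.89), Sct (1.79), Cyp2c65 (1.51), Slc10a2 (1.5), Sprr1a (1.38), Mgat4c (1.36), Fabp2 (1.35), Ugt2b5 (1.14), Zfp758 (1.10), Ugt2b36 (1.01), Slc30a4 (0.74) and Dnajb9 (0.64). Negative ones were found for Itih2 (−2.06), Nxpe4 (−1.90), AI854703 (−1.81), St6galnac4 (−1.72), Adh1 (−1.61), Cyp2d12 (−1.61), B4galnt3 (−1.60), Hid1 (−1.53), Ano1 (−1.29), Lrrc31 (−1.26) and Scnn1a (−0.85).

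Among lists, small intestinal enterocytes (0.93), macrophages (0.75), the antimicrobial list (0.65), xenobiotic metabolism (0.52), absorptive colonocytes (0.46), interferon response (0.39), wound repair (0.37), complexes II and III (0.37), complex IV (0.32), complex I (0.29), proliferation (0.25), fatty acid oxidation (0.21), cell death (0.17) and enteroendocrine cells (0.15) had a higher KO effect under DSS. Water and ion transport (−0.32) and crypt stem cells (−0.30) had a lower one. With an estimated correlation 0 of them passed.

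More genes differed between KO and WT under DSS (84) than in untreated mice (2). For the DSS and the untreated comparisons the 10 splits of 6 libraries are too few for a share under 0.05, and 1 of 10 gave as many genes in each, the real one, with 0 and 1 genes as the highest of the others. For the interaction 2 of 100 splits gave 158 genes or more, the real one and 1 other, a share of 0.02. The other gave 178 with the DSS groups kept apart. The splits therefore cannot exclude chance for the untreated grouping, on which the interaction also rests. A trend with the length of the longest annotated transcript is excluded as the whole cause of the DSS calls. With it taken out 250 genes were called, with 79 of the 84 among them. Bias that does not follow that length was not tested. Libraries from different stretches of colon remain a candidate explanation beside genotype, which was not tested separately: Hox paralog number and fold change had a Spearman's rho of −0.67 across 24 genes under DSS, although most Hoxa genes were lower whatever their number, and with the Hox index as a covariate the called genes kept 67.8% (DSS) and 91.2% (interaction) of their median fold change while calls fell to 1 and 0, with the median log2 change going from 1.0 (SE 0.16) to 0.68 (SE 0.39) and from 1.01 (SE 0.20) to 0.92 (SE 0.23), so that region and genotype cannot be told apart for these genes.

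The respiratory chain lists were higher in KO DSS, with 71 of 74 genes above 0, but with an estimated correlation the adjusted p was 0.59 for ATP synthase and 0.561 for each of the others. The median log2 fold change of these genes (0.37) lay at the 99.99 percentile of 10000 random lists matched on transcript length and expression level. The median of those lists was 0.26. Genes of the random lists were drawn independently, whereas the estimated correlation between genes was 0.80 in complex I and 0.86 in complex IV. The percentile therefore cannot exclude a trend with length and level as the whole cause. The ATP synthase rise alone cannot be told apart from the length trend, because its camera adjusted p was 0.0645 with the trend taken out. Libraries from a more proximal stretch as the whole cause would need respiratory levels to fall with the Hox index. Over the 6 untreated libraries, the relation named in advance, Spearman's rho was 0.89 (exact permutation p = 0.0333, Benjamini-Hochberg adjusted p = 0.0667 over 2 relations). It was 0.8 without the 2 libraries farthest from the median. Pearson's r was 0.62 (exact permutation p = 0.169, adjusted p = 0.308), or 0.29 without them. These values argue against that cause only if the untreated relation holds under DSS. The index of each WT DSS library (0.98 to 1.76) lay above those of the untreated libraries (−0.71 to 0.88). Region stays open beside genotype and the lone weight of KO DSS replicate 1, without which the complex I median was 0.20. Over the 6 DSS libraries, whose groups the index separates, rho was −0.31 (exact permutation p = 0.564, adjusted p = 0.564), or 0 without the 2 farthest. There r was −0.52 (exact permutation p = 0.308, adjusted p = 0.308), or −0.38 without them. The mean respiratory level differed by 0.35 (SE 0.20) in log2 without the index and 0.61 (SE 0.57) with it as a covariate. With that covariate the lists stayed called at the preset correlation.

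C1qa and the macrophage list were higher in KO DSS, but with an estimated correlation the adjusted p of the list was 0.561. More macrophages may be present, as C1qb and C1qc, which macrophages make together with C1qa, were at least 2.13 times as high in KO DSS, although for C1qc the groups overlapped, with KO DSS replicate 1 at 0.075 RPKM and WT DSS replicates 2 and 3 at 0.336 and 0.236. Against macrophages as the source of C1qa, C1qb and C1qc gained at most 11% of the RPKM that C1qa gained, and in untreated WT and KO, in a table that was normalised separately, C1qa had 3.87 and 3.07 RPKM where C1qb had 0.134 and 0.255 and C1qc 0.113 and 0.202, so that WT DSS (0.167) was the low group for C1qa. This source still stays open, because C1qb and C1qc lay near the floor in all groups, and a change of expression within the epithelium was not tested. More leukocytes of all kinds may be present as well, as summed pan-leukocyte reads were 1.27 times as high, and stay open at this spread.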

How the results depend on the processing

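The tests with the Hox index as a covariate, with the transcript length trend taken out, of the lists without each library, and with the stand-ins for other size factors, count tests and a robust fit were chosen only after the data were seen. Planned count tests with edgeR and DESeq2, their size factors and robust fit were not run, although whole reads could be recovered. The fallback that the design states for deposited values other than counts was followed. Median-ratio scaling, limma voom on recovered reads and a robust variance stood for the planned tests. The untreated count of 2 genes was 1 without a filter and 1 with all 12 libraries fitted together. In both settings that gene was lower in KO, so Ndufa4 was not called. The untreated count was 58 at an unadjusted p under 0.05 with the fold limit of the deposited table, and 2 to 6 without each library. Under DSS 0 genes were called higher without a filter, at an adjusted p under 0.01, with the Hox index, or without WT DSS replicate 1 or 2. Ndufa4 was not called in those settings either. The DSS count of 84 was 1 without a filter, 615 with all 12 libraries in one fit, 1 at an adjusted p under 0.01, 41 at a fold of 2 or more, 1 with the Hox index, 250 with the length trend taken out (79 shared with the 84), and 1 to 364 without each library; voom gave 80. The interaction count of 158 was 4 without a filter, 1 at an adjusted p under 0.01, 83 at a fold of 2 or more, 873 at an unadjusted p under 0.05 with the fold limit, 0 with the Hox index (limma, 2152 at an unadjusted p under 0.05 without it), 465 with the length trend taken out, and 1 to 433 without each library. Of the lists, 10 were called in untreated mice, 0 with an estimated correlation, 0 and 5 with fry directional and mixed, 6 with the Hox index, and 4 to 16 without each library. Under DSS 19 were called, 0 with an estimated correlation, 0 and 7 with fry directional and mixed and 11 with the length trend taken out. In the interaction 16 were called, 0 with an estimated correlation, 1 and 10 with fry directional and mixed, 10 with the Hox index, and 10 to 19 without each library. The interaction of Ndufa4 reversed from 0.23 to −0.0075 without KO DSS replicate 1 and reached 0.41 without KO DSS replicate 2. The cause of these changes was not tested, except that stricter thresholds call fewer genes by construction. WT DSS and KO DSS share replicate numbers, and the correlations of deviations at the same number were −0.11, 0.36 and 0.13. KO DSS replicates 2 and 3 correlated best with the WT DSS library of their own number. KO DSS replicate 1 correlated best with WT DSS replicate 3 (0.30). Whether the numbers pair the libraries therefore stays open. A replicate block gave 398 genes, which include the 84, and 20 lists. In untreated mice no block could be fitted because the groups share only 1 number. The lower depth of the DSS libraries limits genes with few reads.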

Other observations

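The DSS value of Slc30a4 was chosen as a test only after its untreated value was seen. Levels under DSS and in untreated mice come from tables that were normalised separately and whose batches cannot be told apart from DSS, so they are set side by side without a test. In WT, small intestinal enterocyte markers had a median log2 level of −0.90 under DSS relative to untreated mice, with 7 of 10 genes below without overlap, xenobiotic genes −0.63 (12 of 27 below) and proliferation genes −0.52 (15 of 30 below). Deep crypt secretory markers had −1.08 and the antimicrobial list 0.40. Over 11306 genes the median was −0.01, and 13% lay above and 17.2% below without overlap, where 10% would by chance in both directions together.

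In KO the same comparison gave 0.23 for small intestinal enterocyte markers, 0.06 for xenobiotic genes and −0.22 for proliferation genes. Crypt stem cell markers had −0.56 with 11 of 12 below, cell death genes 0.44 with 12 of 23 above, wound repair genes 0.54 with 7 of 17 above and complex IV 0.37 with 7 of 13 above. The antimicrobial list had 0.88 with 8 of 21 above. Over all genes 17.2% lay above and 22.0% below without overlap.

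Ndufa4 may rise in KO because it loses repression by miR-147, whose mature form (GUGUGCGGAAAUGCUUCUGCUA) lies at 122640850 to 122640871 on chromosome 2. Its 3′ UTR of 246 bases holds 1 copy of the seed match CCGCACA, which the hypothesis needs, at 11900476 to 11900482 on chromosome 6. Other genes with a seed match were not higher as a group under DSS, where their mean difference lay above only 10.2% of 59 control 7-mers. In untreated mice the difference lay above 42.4%. The control 7-mers were not matched on 3′ UTR length, and the trend with transcript length was not taken out. A small effect on these genes therefore stays open in both comparisons.

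Slc30a4, which lies 40.0 kb from AA467197, might be lower in untreated KO through the deletion itself. Under DSS it was not lower in KO, with a log2 fold change of 0.38 (SE 0.12). This cannot exclude a lasting effect, because the Hox index also separates the DSS groups and another difference between them could cover it. Genes within 5 Mb of the locus had an unadjusted p under 0.05 in 5.94% of 101 cases, against 9.06% elsewhere (Fisher's exact test, one-sided, p = 0.904), which does not rule out an effect on single neighbours.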
